A study of Homo sapiens with 14 samples.

How the data were processed

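The series measured N6-methyladenosine (m6A), a methyl mark on messenger RNA, in CHP-212 cells, an established human neuroblastoma line. The assay was miCLIP, in which fragmented poly(A)+ RNA is bound by an anti-m6A antibody, crosslinked to it with ultraviolet light and sequenced. Per the labels, 9 libraries came from anti-m6A immunoprecipitation (IP), with 3 each from unmodified control cells, cells overexpressing METTL14 and a group named an ALKBH5 rescue. A further 5 libraries were 1 input per group, 1 with rabbit IgG in place of the antibody and 1 made from water. Per the labels' protocols, METTL14 and ALKBH5 were delivered as lentiviral constructs under a CMV promoter. As the controls were unmodified cells, no comparison with control can tell the delivered gene apart from the lentiviral delivery. The labels do not say what the ALKBH5 group was rescued from. The replicates are described as biological samples, but nothing says that they came from separate cultures, so p-values measure the spread between these samples, which may be technical.

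The deposited data were 14 lists of read clusters, 1 per library and not pooled, on genome build GRCh38.p12. Per the submitters' processing notes, CASAVA 1.8, cutadapt 1.18 and STAR (version not given) were used. The peak caller, its settings and any removal of duplicate reads are not given in the sources used here. Each deposited cluster name ended in a whole number of at least 3, which was read here as the number of reads in that cluster. Each cluster also had a p-value from the authors' caller, and all deposited p-values were under 0.05; whether they were adjusted is not stated. Across the clusters of control IP 1, which are not independent, the Spearman correlation of this number with the negated p-value was 0.976. Repeated intervals were kept once. The files held a cluster number for each gene, so clusters outside genes were nearly absent by construction. Adjoining clusters often carried the same number (80.8% of touching pairs in control IP 1), so sums over clusters count some reads more than once.

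The reads in clusters, which are not the sequencing depth, numbered 4065488, 1900436 and 2347552 in the control IP libraries 1 to 3. They numbered 2857397, 6269536 and 3176952 in the METTL14 IP libraries and 820769, 2546955 and 4219200 in the ALKBH5 IP libraries. The inputs held 582544 (control), 2254 (METTL14) and 580471 (ALKBH5), IgG 194388 and water 17499. The total reads of the libraries are not given in the sources used here. The METTL14 input, with 623 clusters, fell under a minimum of 5000 clusters and was left out of the fits. Shares of single libraries carry 95% Wilson intervals, which cover counting error only, since reads can be PCR copies.

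Each cluster was assigned by its midpoint and strand to a gene of GENCODE release 29, with exons before introns and protein-coding genes before others. Clusters still open between several genes held 5.47% of reads and were left out of gene sums. The assigned gene was the one named in the file for 98.2% of clusters. IGF2 (ENSG00000167244.19) overlaps another annotated gene on its strand, so the clusters in its 3' part belong to this ambiguous set at the gene level. For the cluster level, overlapping clusters of the 9 IP libraries on 1 strand were merged into 1235621 regions, of which 113910 were called in at least 3 libraries. A gene or region was tested if its scaled reads (RPM) exceeded what 10 reads make in the median library (3.743 for genes, 4.244 for regions) in at least 3 libraries, with at least 15 reads in all. This left 14180 genes and 45119 regions.

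The planned test assumed read counts per cluster in the score column. That column held p-values, so the stated fallback was used on the read numbers in the cluster names, and count-based tests were not run. The fallback was limma 3.58.1 in R 4.3.3 on log2(RPM + 1), scaled to the column sum of the table tested, with a mean-variance trend, 1 fit over the 9 IP libraries, no covariate and Benjamini-Hochberg adjusted p under 0.05. Folds on this scale understate the change of low genes. IP was compared with the 2 usable inputs in 1 fit with a term for the IP and 1 for the group, which left 7 residual degrees of freedom. Single genes and regions against a group with 0 reads in every library are given as reads or RPM with no fold, since the lowest number reported differed between genes and libraries.

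Groups of genes were fixed before the data were examined, as were the tests, the other settings and the rule for named genes. There were 14 written lists (m6A writer complex, m6A erasers and readers, adrenergic neuroblastoma identity, mesenchymal neuroblastoma identity, neuronal differentiation and axon, neural crest and Schwann, mitosis and proliferation, p53 and apoptosis, interferon and RNA sensing, MYC targets and translation, immediate early and stress, nuclear long noncoding RNA, fibroblast markers, and blood and endothelium markers). A further 3 came from name patterns (cytosolic ribosomal proteins, histones and mitochondrially encoded genes). Lists were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation beside it, and with fry, each adjusted over the 17 lists.

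The rule named METTL14 and ALKBH5 first. For each comparison with control it took the 8 largest rises and 8 largest falls among genes past the threshold. These had all 3 libraries of a group on 1 side of the other's and a mean above the median of tested genes (log2 of 4.59). Where fewer passed, genes next by p filled up to 4 per direction, as values that did not pass. It also took the 2 members of each list with the smallest p. For ALKBH5 against METTL14 it took 5 per direction, for regions 3 per direction, for IP against input the 10 largest rises, and for IgG the 5 genes with most reads. Some items that the rule named are not reported here.

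Shares of reads by annotation were taken from cluster midpoints. The stop codon share is the part of coding and UTR reads in clusters with a midpoint within 200 nt of an annotated stop codon. The DRACH share is the part of clusters with this m6A consensus (D is A, G or T; R is A or G; H is A, C or T) within 10 nt of the midpoint, with the same window 100 nt upstream as background. No genome was used here, so the motif was read from transcript sequences of release 29 for exonic clusters, 92.4% of which had a full window; the plan had set the motif aside in this case. These shares were compared between groups by exact two-sided permutation tests over 20 arrangements, with Benjamini-Hochberg adjustment over 21 tests. Overlaps were computed with bedtools 2.31.1 (at least 1 base, same strand), and other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

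The limma step was tested on simulated data for METTL14 against control, with 200 changed genes among 14180 or 200 changed regions among 45119. It called 1.59% of genes changed 2-fold, 42.4% of those changed 4-fold and 59.2% of those changed 8-fold, with 2 false calls. For regions it called 0%, 1.69% and 6.85%, with 0 false calls. Alternatives covered scaling, filters, samples in the fit, a replicate block, thinning, a minimum of 5 reads per cluster, background clusters, exons, the 10 largest genes, gene assignment, merging distance, pseudocount, weights, and each library left out in turn. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom from 10.8 to 30.8 over genes), so all were counted separately.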

Results

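Clusters of m6A miCLIP reads were compared between control CHP-212 neuroblastoma cells, cells overexpressing METTL14 and an ALKBH5 rescue group, with 3 IP libraries each. METTL14 is a subunit of the methyltransferase that writes m6A, and ALKBH5 is a demethylase that removes it. An IP library held between 820769 and 6269536 reads in clusters. The smallest, ALKBH5 1, stood apart from the others: across genes, its Spearman correlations with the other IP libraries ran from 0.784 to 0.841, 0.818 and 0.825 within its own group, against 0.859 to 0.929 among the others. It lay at 174 on the first principal component (36.9% of variance), and the others between −54.4 and 7.94. All values are reads in reported clusters, so they reflect both the methylation and the abundance of a transcript. Fold changes are on the log2(RPM + 1) scale, errors are standard errors (SE) of the fit for folds and SD for means, and n is 3 libraries per group.

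The overexpressed genes were read first. METTL14 (ENSG00000145388.14, chromosome 4, 118685368 to 118715433) stood at 36.2, 35.7 and 30.1 RPM in the control IP libraries 1 to 3. In the METTL14 IP libraries it stood at 228, 559 and 293 RPM, and in the ALKBH5 IP libraries at 30.9, 33.98 and 18.3 RPM. The METTL14 rise lay in the coding sequence, with 603, 3273 and 863 reads, and the 3' UTR held 0 reads in each METTL14 IP library against 37, 21 and 40 in the controls. ALKBH5 (ENSG00000091542.8, chromosome 17, 18183078 to 18209954) stood at 97.2, 150 and 85.3 RPM in control IP, at 68.9, 91.2 and 62.2 RPM in METTL14 IP and at 2035, 1825 and 2367 RPM in ALKBH5 IP. Coding sequence again held most of it, with 1530, 4329 and 9176 reads in the ALKBH5 IP libraries. The single ALKBH5 input held 424 RPM of ALKBH5 and the control input 125 RPM, and IgG held 598 RPM of ALKBH5 (112 reads) and 256 RPM of METTL14 (48 reads). For both genes the IgG value lay above each control IP library, and for METTL14 also above METTL14 IP 1.

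**Figure D1:**
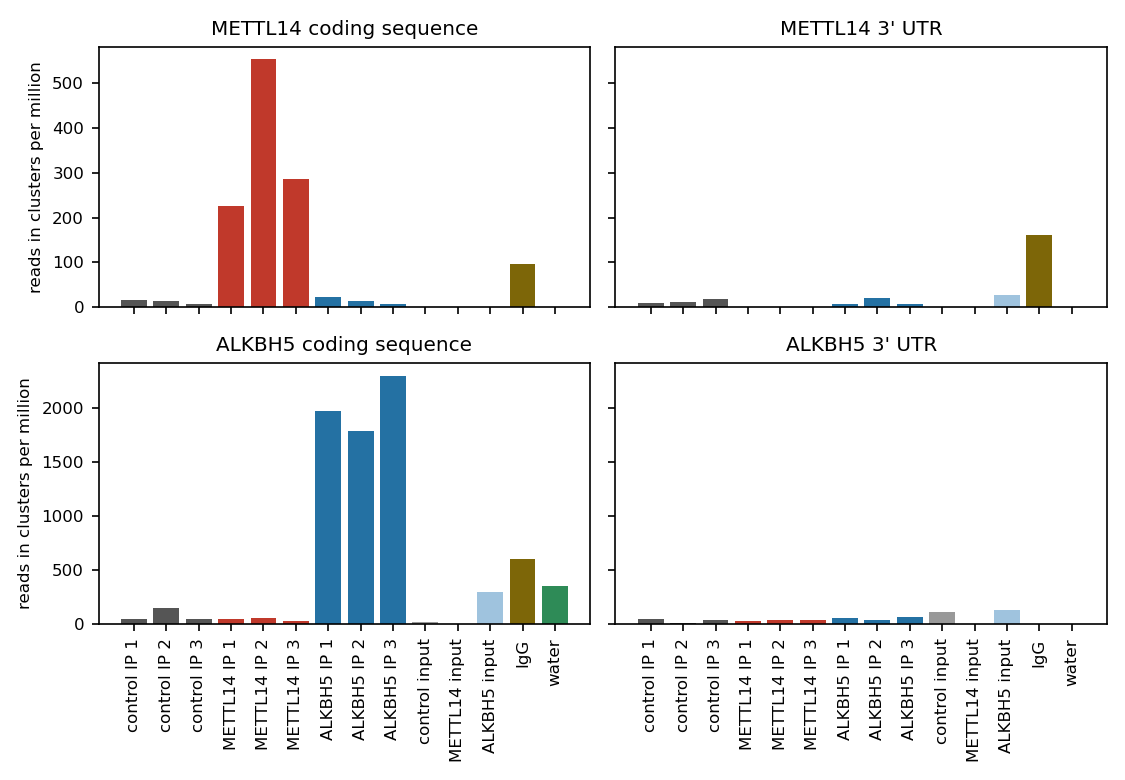
RPM of METTL14 and ALKBH5 in coding sequence and 3' UTR in each of the 14 libraries, 1 bar per library. The METTL14 IP libraries reach 226, 553 and 287 RPM in METTL14 coding sequence and the ALKBH5 IP libraries 1972, 1794 and 2303 RPM in ALKBH5 coding sequence.

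The IP libraries were compared with inputs to see which transcripts the antibody step enriched. Of 14138 genes tested, 3872 were higher and 869 lower in IP than in input (limma, adjusted p under 0.05), and 2272 of the higher genes had no input reads. Over all tested genes, 4177 had no input reads. The filter asked for at least 3 libraries, so a gene seen only in the 2 inputs could not be tested. The balance of higher and lower genes, here and in the lists below, is thus partly built in. Both inputs also held fewer reads in clusters than any IP library. The 10 genes with the largest rises had reads in all 9 IP libraries and none in either input. RNA5SP152, a 5S ribosomal RNA pseudogene, averaged 219 ± 70.5 RPM in IP (SD, n = 9). HMX1, a homeobox transcription factor, averaged 175 ± 51.4 RPM and SAC3D1 142 ± 30.1 RPM. The means of the others were 129 RPM for L3MBTL2, 126 for GNAZ, 125 for RPUSD1, 118 for FIS1, 116 for the complex I subunit NDUFA13, 110.2 for PWWP2B and 108 for ZNHIT1. The lists were counted here and not tested as lists. Of the immediate early and stress genes 11 of 20 were higher and 0 lower, of the histones 16 of 43 higher and 2 lower, of interferon genes 7 of 15 and 2, of the p53 list 7 of 19 and 2, of adrenergic genes 6 of 17 and 2, of m6A writers 5 of 12 and 0, of neural crest 3 of 6 and 0, and of nuclear noncoding RNA 2 of 12 and 0. More were lower than higher among the mitochondrially encoded genes (8 lower and 1 higher of 13), mitosis (6 and 1 of 24), ribosomal proteins (18 and 15 of 83), MYC targets (6 and 5 of 20) and fibroblast markers (3 and 1 of 10). The counts were 5 higher and 4 lower of 24 mesenchymal genes, 4 and 4 of 18 neuronal genes, 3 and 3 of 17 erasers and readers, and 0 and 0 of 2 blood and endothelium markers. Only 2 inputs, 1 each of control and ALKBH5, entered this fit. With the IP libraries thinned to the smallest of them, the gene-level IP versus input fit called 2160 genes.

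Most reads of the 9 IP libraries lay in coding sequence (51.1% ± 3.10, SD), 3' UTR (29.1% ± 1.41) and introns (13.4% ± 4.01). Around stop codons, the usual place of m6A, IP libraries held 27.6% ± 0.695 of coding and UTR reads. The control input held 18.2% (95% Wilson interval 18.1 to 18.4), the ALKBH5 input 17.4% (17.3 to 17.5) and IgG 21.2% (21.0 to 21.4). This contrast rested on weighting by reads: with each cluster counted once, the IP libraries held from 15.4% to 18.7%, the control input 15.9%, the ALKBH5 input 15.3% and IgG 20.7%. In clusters of at least 20 reads, DRACH lay within 10 nt of the midpoint in 36.3% ± 1.32 of IP clusters against 28.6% ± 0.405 at the upstream window. The related GGAC, searched with any base after it, lay there in 15.3% ± 0.889 of IP clusters. It lay there in 7.63% (6.87 to 8.46) of control input clusters and 8.44% (7.64 to 9.31) of ALKBH5 input clusters. In IgG the GGAC share was 14.6% (12.4 to 17.2), which included the IP mean. At the upstream window GGAC was also more frequent in IP, at 9.83% ± 0.367. There the control input held 7.88% (7.11 to 8.73), the ALKBH5 input 7.33% (6.58 to 8.15) and IgG 10.2% (8.30 to 12.4). Over exonic clusters of any read number the GGAC contrast at the midpoint was smaller, at 10.7% ± 0.585 in IP. The control input then held 7.39% (7.13 to 7.66), the ALKBH5 input 8.11% (7.85 to 8.37) and IgG 10.8% (10.3 to 11.3). The genes with most reads over the IP libraries were EEF2 (9781 ± 3157 RPM, SD, n = 9), MT-CO2, GAPDH, DDX1 and PKM.

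**Figure D2:**
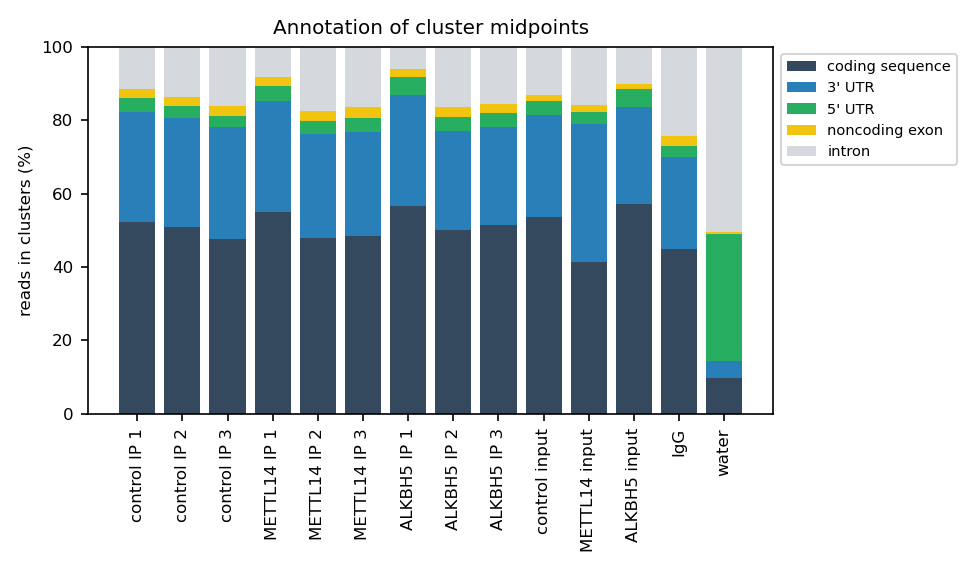
Percent of reads by the annotation at the cluster midpoint in each of the 14 libraries, as stacked bars. In the 9 IP libraries coding sequence holds 47.8% to 56.6% and introns 6.13% to 17.4% of reads.

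**Figure D3:**
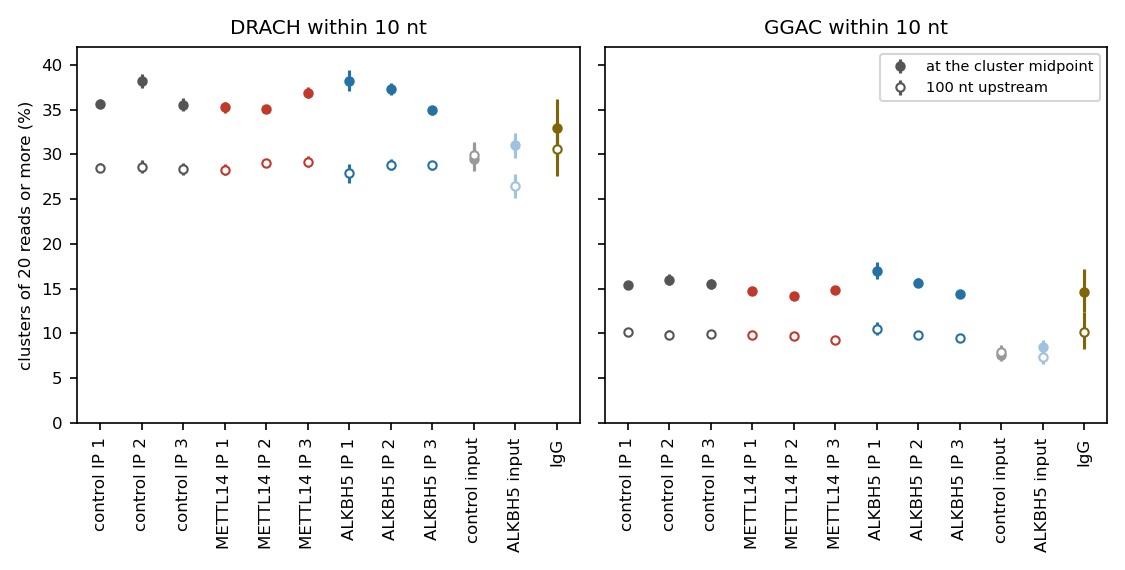
Percent of clusters of at least 20 reads with DRACH or GGAC within 10 nt of the midpoint (filled) and of a point 100 nt upstream (open), per library, with 95% Wilson intervals as bars. Over the 9 IP libraries, the DRACH mean is 36.3% at the midpoint and 28.6% upstream.

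The comparison of METTL14 overexpression with control asked which transcripts gain or lose m6A reads when a writer subunit is raised. METTL14 itself was the 1 gene that rose, by a log2 fold of 3.26 ± 0.350 (SE; limma adjusted p = 0.00419), and 0 genes fell. No gene other than METTL14 passed limma's threshold, and 551 of 14180 had an unadjusted p under 0.05 (3.89%). The genes next by p had log2 folds of 1.93 for the imprinted gene NNAT, 1.37 for the ribosomal protein gene RPS6 and 1.19 for the fatty acid receptor CD36. On the lower side they had −2.14 for OBP2A, −1.44 for the lactate transporter SLC16A3 and −1.37 for STAT6, and the smallest adjusted p among these 6 was 0.0944.

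None of the 17 lists passed for METTL14 against control (camera, smallest adjusted p = 0.133, for nuclear long noncoding RNA and for cytosolic ribosomal proteins; 0.845 for both with an estimated correlation; fry also called 0). The unadjusted p was under 0.05 for 3 lists. Adjusted over the list alone, 1 of 12 members of the m6A writer complex was higher, METTL14, as over all genes. Likewise adjusted over the list alone, 1 of 17 adrenergic identity genes was lower, TH, the rate-limiting enzyme of catecholamine synthesis (log2 fold −1.63), and 1 of 83 ribosomal protein genes was higher, RPS6. Over all genes neither passed. In the other 14 lists the count was 0 both adjusted over the list alone and over all genes. Values of members that did not pass included, as log2 folds, METTL16 −0.35, ALKBH5 −0.55, HNRNPA2B1 0.42, GATA3 −0.62, NOTCH1 −0.72, FOSL2 −0.75, SYT1 1.14, TFAP2A −0.51 and NGFR −0.35. Others were TOP2A 0.66, AURKA 0.79, MCL1 0.33, MDM2 0.47, IFIT5 1.20, EEF1A1 0.73, NPM1 0.77, ATF4 0.84, JUND −0.42, MEG3 1.32 and GAS5 0.58. Among markers of other cell types and the pattern lists they were COL6A2 −0.83, LUM 0.60, CD68 −1.09, VWF −0.26, RPS12 0.62, HIST1H3J −1.90, H2AFJ −1.03, MT-ND6 0.57 and MT-CO2 −0.27. The signs of median, mean and camera differed for the p53 list (median negative, mean positive, camera down), the mitochondrial list (both positive, camera down) and the neuronal list (median negative, mean positive, camera up). Without METTL14 2 or METTL14 3, 1 list passed.

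The METTL14 and control libraries did not overlap in 1462 of 14180 genes (10.3%), where chance gives 10%. The call of METTL14 was kept in each fit with 1 library left out except that without control 2, where its log2 fold was 3.30 and 0 genes passed; the count was 4 without ALKBH5 1 and 2 without control 3.

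The comparison of the ALKBH5 rescue group with control asked which transcripts differ when an m6A demethylase is supplied. Its supply cannot be told apart here from the lentiviral delivery, which the unmodified controls lacked. Reads rose for 9 genes and fell for 7 (limma, adjusted p under 0.05). Besides ALKBH5, with a log2 fold of 4.25 ± 0.248 (SE; adjusted p = 2.07e-06), the largest rises were PKIB, an inhibitor of protein kinase A (chromosome 6, 122471917 to 122726373), at 4.70 ± 0.610 (adjusted p = 0.0113) and ADAM19, a membrane metalloprotease (chromosome 5, 157395534 to 157575775), at 3.26 ± 0.341 (adjusted p = 0.00157). NNAT rose by 2.92, the matrix gene THBS4 by 2.80, the neuronal membrane gene LINGO1 by 1.93, the receptor for vasoactive intestinal peptide VIPR1 by 1.90 and the plasminogen activator gene PLAT by 1.57. Reads of IGF2 (ENSG00000167244.19), a fetal growth factor gene at chromosome 11, 2129112 to 2149603, fell by 2.12 ± 0.325 on the log2 scale (adjusted p = 0.0254). The collagen gene COL5A1 and the homeobox gene PRRX2 also fell by 2.12, OBP2A fell by 2.07, the transcription factor gene ATOH8 by 1.98 and the cadherin gene CELSR3 by 1.67. The other called genes, which fell outside the naming rule or past its number and were named after their values were seen, were SPATS2L at 1.38 and SEZ6L2 at −4.56. SEZ6L2 stood at log2 values of 0, 0 and 1.33 in the ALKBH5 libraries, so its fold rests on values near 0. In COL5A1, PRRX2, OBP2A and CELSR3 the METTL14 libraries also lay below every control, and in NNAT above every control. None of these genes was called between ALKBH5 and METTL14. OBP2A had log2 values of 4.80, 5.03 and 4.19 in METTL14 and 4.67, 4.62 and 4.95 in ALKBH5. In the remaining called genes the METTL14 and control libraries overlapped.

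Of the 15 called genes other than ALKBH5, 13 had input reads, and the ALKBH5 to control ratio of the single inputs had the sign of the IP change in 12 of them, SPATS2L being the exception. The count ranged from 2 to 48 with 1 library left out, being 3 without control 1, 2 without control 2 or ALKBH5 2, 8 without control 3 and 48 without ALKBH5 1, the library that stood apart. It was 42 for exonic clusters alone. The call was lost in 5 of the 9 fits with a library left out for VIPR1, PLAT, IGF2 and OBP2A, and in 6 for PRRX2 and CELSR3.

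**Figure D4:**
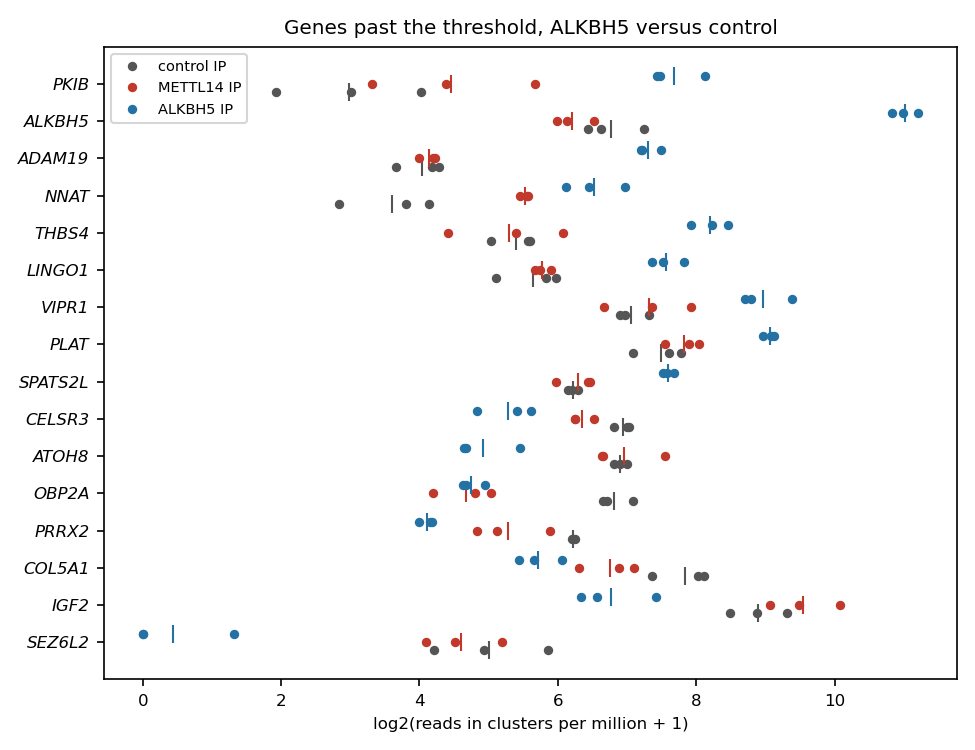
Log2(RPM + 1) of the 16 genes called between ALKBH5 rescue and control, 1 point per IP library in the 3 groups, with the group mean as a vertical tick. PKIB lies between 7.43 and 8.12 in the ALKBH5 libraries and between 1.92 and 4.02 in the controls, and COL5A1 lies between 5.43 and 6.06 against 7.36 to 8.11.

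Among the lists, the 13 mitochondrially encoded genes were lower together in ALKBH5 than in control, with a median log2 fold of −0.44 and 13 of 13 negative (camera adjusted p = 0.0229; adjusted p = 0.537 with an estimated correlation). MT-ND2 had a log2 fold of −0.85 and MT-ATP6 of −0.88, and 0 members passed alone or over all genes. Mitochondrial genes held 4.60%, 4.37% and 3.36% of gene reads in the control IP libraries and 3.29%, 2.71% and 2.35% in the ALKBH5 IP libraries, with 7.20% in the control input and 3.98% in the ALKBH5 input. The mitosis list was higher, with 16 of 24 members positive and a median of 0.13 against −0.13 over all genes (camera adjusted p = 0.0352; adjusted p = 0.379 with an estimated correlation). Its members with the smallest p were TOP2A at 0.87 and the kinetochore motor CENPE at 1.51. The interferon list was also higher, with 11 of 17 positive and a median of 0.39 (camera adjusted p = 0.0352; adjusted p = 0.379 with an estimated correlation), led by the antiviral genes MX1 at 1.96 and OAS3 at 2.08. In neither list did a member pass, adjusted over the list alone or over all genes, and fry, which tests a list by itself, called 0 of the 17 lists. The 4 at an unadjusted fry p under 0.05 were adrenergic identity, neural crest, MYC targets and histones. For the mitochondrial, mitosis and interferon lists the unadjusted fry p was 0.0717, 0.0621 and 0.0801. The number of lists called was 0 without control 1 or ALKBH5 3 and 1 without control 2, control 3, METTL14 2 or METTL14 3.

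Adjusted over the list alone, 3 of 17 adrenergic identity genes were lower and 0 higher, against 0 over all genes. They included TH (log2 fold −2.35; adjusted p = 0.0515 over all genes) and the transcription factor GATA3 (−0.91). Adjusted over the list alone, mesenchymal identity had 1 higher, FOSL2 at 1.28, and 1 lower. Adjusted over the list alone, 1 gene was lower in each of 4 further lists, namely MAP2 (−1.72) of the neuronal genes, TFAP2A (−1.63) of neural crest, EIF4A1 (−0.99, but 0.23 with each cluster given to the gene named in the files) of the MYC targets and MEG3 (−3.57) of the nuclear noncoding RNAs. None of these passed over all genes. MEG3 stood at log2 values of 0, 1.17 and 0 in the ALKBH5 libraries, so its fold rests on values near 0. ALKBH5 was the 1 of 17 erasers and readers past both adjustments. The count was 0 by both adjustments for the m6A writers, p53 and apoptosis, immediate early and stress, fibroblast, blood and endothelium, ribosomal protein and histone lists. Values of members that did not pass were RBM15 −1.13, WTAP 0.36, HNRNPA2B1 0.47, NEFL 1.08, MITF −1.66, SESN2 −1.20, BAK1 0.85, CCT2 0.57, EGR1 1.05, ATF4 0.67 and NEAT1 −0.63. The others were ACTA2 −2.44, COL6A2 0.61, VWF −0.39, CD68 −0.09, RPL39L −2.52, H1F0 1.06 and HIST2H2AC −2.16. The median and mean were negative while camera's direction was up for the mesenchymal, p53 and ribosomal protein lists.

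The direct comparison of ALKBH5 rescue with METTL14 overexpression set the eraser group against the writer group. Reads were higher for 24 genes in ALKBH5 and lower for 16 (limma, adjusted p under 0.05). ALKBH5 rose by a log2 fold of 4.80 ± 0.248 (SE; adjusted p = 4.22e-07) and METTL14 fell by 3.59 ± 0.350 (adjusted p = 0.000450). Other genes that rose were the calcium-binding protein gene S100A2 at 3.38, the lipid droplet gene PLIN4 at 3.38 and PKIB at 3.22. Other genes that fell were TMOD1, which fell by 3.14, and CHODL, which fell by 2.81. IGF2 fell by 2.77 on the log2 scale (SE 0.325; adjusted p = 0.00239) and its antisense transcript IGF2-AS fell by 2.35. The calls of TMOD1 and IGF2-AS were each lost in 8 of the 9 fits with a library left out, that of PKIB in 7 and that of CHODL in 5.

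The mitosis list was higher in ALKBH5 than in METTL14, with 18 of 24 positive and a median of 0.25 (camera adjusted p = 0.00859; adjusted p = 0.340 with an estimated correlation). The mitochondrially encoded list was lower, with 13 of 13 negative and a median of −0.47 (camera adjusted p = 0.0137; adjusted p = 0.536 with an estimated correlation). Fry called 0 lists, and the 3 at an unadjusted fry p under 0.05 were adrenergic identity, nuclear noncoding RNA and mitosis. Adjusted over the list alone, mesenchymal identity had 3 higher and 1 lower of 24 against 1 higher and 0 lower over all genes. Adjusted over the list alone, 1 adrenergic and 1 neuronal gene were lower against 0 of each over all genes. By both adjustments, 1 writer (METTL14), 1 nuclear noncoding RNA and 1 ribosomal protein gene were lower, and 1 eraser (ALKBH5) and 1 fibroblast marker were higher. The count was 0 by both for the 9 other lists. Camera's direction was up while median and mean were negative for the mesenchymal and p53 lists, and for the neuronal list the median was 0.25 and the mean −0.04. The number of lists called was 1 without METTL14 3 or any 1 of the ALKBH5 libraries.

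With 1 library left out, between 8 and 74 genes passed between ALKBH5 and METTL14, namely 16, 18 and 31 without control 1, 2 and 3, 17, 17 and 10 without METTL14 1, 2 and 3, and 74, 8 and 14 without ALKBH5 1, 2 and 3. Exonic clusters alone gave 74 genes, and a fit of only these groups gave 10.

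Single regions with reads in 1 group and 0 in another were called too, and since clusters were reported only from a minimum that is not known for each gene, they are given as reads with no fold. A region in the coding sequence of MT-ND3, a mitochondrial complex I subunit (chromosome M, 10134 to 10179), had 572, 1574 and 949 reads in METTL14 IP, 169, 409 and 1210 in ALKBH5 IP and 0 in the 3 controls. It was called higher than in control in METTL14 (limma adjusted p = 1.28e-08) and in ALKBH5 (adjusted p = 2.14e-08). For this and the other regions at 0 in a group, the fit took an unreported region as an exact 0. Such a group has no spread, so these p-values do not measure its variation. The controls had other MT-ND3 clusters, and the number expected in the region was at most 0.873 times the lowest number reported in that gene. Without the antibody, the control input had clusters of 280 and 316 reads over this region and the ALKBH5 input 235 and 216. The IP values of regions are sums over clusters, which may count reads more than once. In MT-ND3 the 1574 of METTL14 IP 2 joined adjoining clusters of 804 and 770 reads, and the 1210 of ALKBH5 IP 3 those of 620 and 590. In ACTG1, the cytoplasmic gamma actin gene, a coding region (chromosome 17, 81510929 to 81510960) had 667, 169 and 138 reads in control, 450, 323 and 437 in METTL14 and 0 in the ALKBH5 libraries. The number expected in the ALKBH5 libraries was as low as 1.60 times the lowest number reported in that gene. The control input had clusters of 56 and 76 reads in this ACTG1 region. The ALKBH5 input had none there, so its gap was also present without the antibody. A region of the IGF2 3' UTR (chromosome 11, 2131087 to 2131159) had 284, 117 and 126 reads in control, 359, 369 and 319 in METTL14 and 0 in ALKBH5. A region of the COL1A1 3' UTR (chromosome 17, 50184916 to 50184950) had 239, 115 and 136 reads in control, 231, 397 and 117 in METTL14 and 0 in ALKBH5. These 3 were lower in ALKBH5 than in control (limma adjusted p = 5.10e-06 for ACTG1 and IGF2 and 9.06e-06 for COL1A1) and than in METTL14 (adjusted p = 3.80e-06, 3.80e-06 and 7.79e-06). With limma voom weights, an alternative chosen after the data were seen, the call of MT-ND3 in METTL14 was lost, as were those of ACTG1, IGF2 and COL1A1 against control and of ACTG1 against METTL14.

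**Figure D5:**
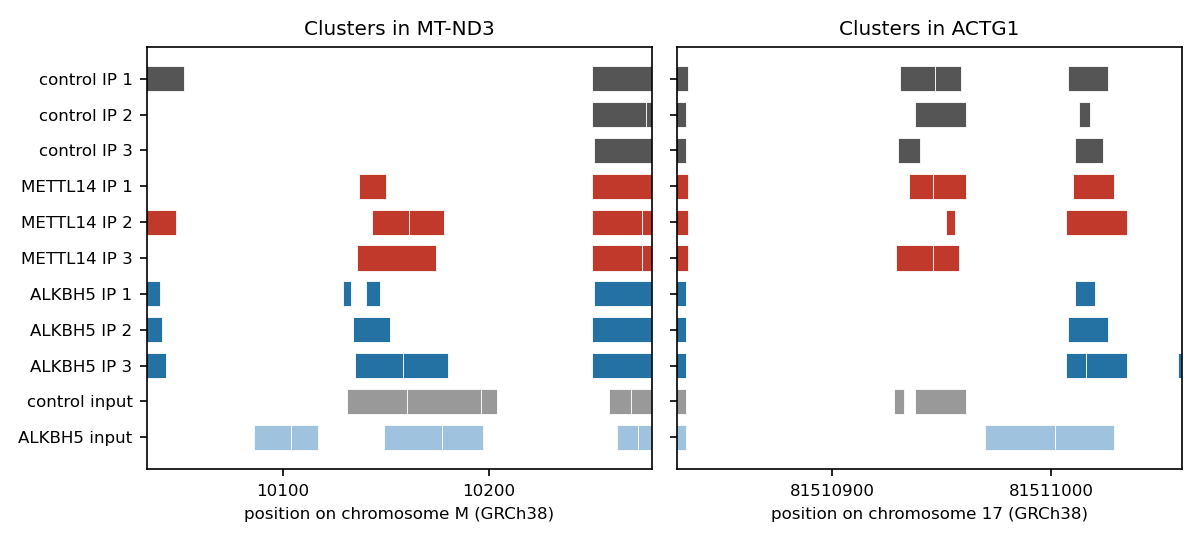
Clusters of the MT-ND3 region of chromosome M and the ACTG1 region of chromosome 17 in the 9 IP libraries and 2 inputs, with position in nt on the x axis and bars for called clusters (white lines part touching ones). The ACTG1 region from 81510929 to 81510960 holds 0 reads in the 3 ALKBH5 libraries and 138 to 667 in the controls.

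Between METTL14 and control, 4 regions were higher and 3 lower of 45119 tested (limma, adjusted p under 0.05; 2143 at an unadjusted p under 0.05). A region of the EID1 3' UTR (chromosome 15, 48879164 to 48879215) was higher, with 57, 95 and 91 reads in METTL14 and 0 in control (adjusted p = 0.00979). The number expected in control was as low as 1.15 times the lowest number reported in that gene. This EID1 region also had 33, 80 and 100 reads in ALKBH5 and was called higher there than in control (limma adjusted p = 0.000943). A coding region of PCYT2 (chromosome 17, 81904853 to 81904944) was higher, with 65, 156 and 43 reads against 0 (adjusted p = 0.0393). It had 11, 52 and 33 reads in ALKBH5, and its call was lost in 8 of the 9 fits with a library left out. A coding region of COL6A2 (chromosome 21, 46111979 to 46112043) was lower, with 401, 28 and 36 reads in control and 0 in METTL14 (adjusted p = 0.00979). It had 142, 316 and 226 reads in ALKBH5, and the ratio of expected to lowest reported reads was as low as 1.29. With voom weights 0 of the 7 regions were called, and the calls of EID1, PCYT2 and COL6A2 were also lost after thinning and in a fit of only these groups. Between ALKBH5 and control 10 regions were higher and 14 lower. Among them were coding regions of ALKBH5 on chromosome 17, at 18194955 to 18195035 (log2 fold 7.13) and 18206815 to 18206971 (6.24). The first had 0, 32 and 0 reads in control. Its call was lost with voom weights and in 3 of the 9 fits with a library left out. Between ALKBH5 and METTL14 19 were higher and 21 lower. An intronic region of PDE7B (chromosome 6, 136160217 to 136160240) was higher, with 570, 82 and 228 reads against 0 in METTL14 and 189, 22 and 0 in control (adjusted p = 0.0276), a call lost in 7 of the 9 fits with a library left out and with voom weights, and the 570 came from the smallest library. The METTL14 count was 20 without control 1, 2 without METTL14 1 and 4 without METTL14 3, and the ALKBH5 to METTL14 count was 24 without METTL14 1, 25 without ALKBH5 2 and 26 without ALKBH5 3.

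Because METTL14 and ALKBH5 were compared with the same controls, their fold changes correlate by chance. Across genes, which are not independent replicates, r was 0.408 against 0.4998 in 100 simulations of unchanged groups, and the covariance was 0.231 against 0.278. The sign was the same for 63.6% of genes against 66.7% simulated. The controls could not be split with 2 libraries per part, so shared controls may account for these values. Between the ALKBH5 comparisons with control and with METTL14, which share the ALKBH5 libraries, 8 called genes were higher in both (ALKBH5, PKIB, ADAM19, THBS4, LINGO1, VIPR1, PLAT and SPATS2L) and 3 lower in both (IGF2, ATOH8 and SEZ6L2). In 100 simulations of unchanged groups they shared 0 called genes, but those simulations called only 0.02 and 0.01 genes on average. Independent lists of the real lengths would share 0.0152 and 0.00790, which leaves out the shared libraries, so part of the excess may come from them.

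The amount of clusters and their shares by annotation, motif and background showed no detectable difference between groups, in tests that could not give a p under 0.1. Control IP libraries held 224607 ± 55172 clusters (SD, n = 3), METTL14 304389 ± 123289 and ALKBH5 218425 ± 125617, covering 6130562, 8514197 and 6056245 nt on average with 2771159, 4101295 and 2528975 reads. Reads in 3' UTR made up 30.1% ± 0.303 in control, 29.05% ± 1.11 in METTL14 and 28.1% ± 1.89 in ALKBH5. The stop codon share was 27.9% ± 0.868, 27.5% ± 0.931 and 27.4% ± 0.323 in the same order, and the DRACH share over all exonic clusters 33.5% ± 0.518, 33.3% ± 0.312 and 33.6% ± 0.509. Clusters that overlapped an IgG, water or input cluster held 44.2% ± 2.03, 44.1% ± 6.53 and 46.6% ± 4.79 of reads. Of the 21 exact two-sided permutation tests between groups, the smallest p was 0.2 (adjusted 0.84), and 3 libraries against 3 cannot give a p under 0.1. Pairs of libraries within a group shared 27.6% of clusters and pairs between groups 27.3%, a difference of 0.316 points (permutation p = 0.0786 over 280 regroupings). This difference was −0.290 without ALKBH5 2 and −0.229 without ALKBH5 3. With the same number of top clusters from each of the 9 libraries it was 0.468 (permutation p = 0.0357).

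In IgG, 5807 genes held reads, and the 10 largest held 8.66% of gene reads. ACVR2B, an activin receptor gene, held 4.93%, followed by APOC3 (0.603%), MTPN (0.513%), EEF2 (0.415%) and DDX1 (0.404%).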

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

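No test was run here, and the library was looked at because it is in none of the groups compared. The library made from water, which should hold no RNA, had 17499 reads in 1472 clusters. The comparisons between groups used its clusters only as background, in the background overlap and in the fits without clusters overlapping IgG or water. ERCC1 held 33.8% of its gene reads, AP1B1 8.66% and LINC01331 5.67%, and ALKBH5 had 6 reads.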

How the results depend on the processing

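The alternatives chosen after the data were seen were the other pseudocounts, voom weights, the largest number of each run of touching clusters in place of their sum, the gene as named in the files, IP thinning and ratio scaling against input, the motif at the cluster summit, and for the lists ratio scaling, the lists without METTL14 and ALKBH5, and each library left out. The alternatives with DESeq2, and those with its size factors or TMM in edgeR, were not run because the files held no count column; total scaling alone equals the scaling used. Of 372 alternatives for 32 counts and shares, 272 stayed within their limits, 71 moved, 28 reversed and 1 became stronger. Of 2554 alternatives for 127 single genes and regions, 2326 kept direction and side of the threshold, 191 lost the call, 25 gained one and 12 reversed. ALKBH5 kept its call in every alternative of both its comparisons, and the gene-level METTL14 versus control log2 fold of METTL14 kept its call in all but the fit without control 2 (adjusted p = 0.0516). Where a value moved, the cause was not tested. At the depth here the simulated test called 1.59% of genes changed 2-fold, so changes of that size were mostly not detectable.

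For genes between METTL14 and control (1 called), 2 were called with no filter, 6 after thinning to the smallest library, 2 from clusters of at least 5 reads, 3 from exonic clusters, 3 with the largest number of touching clusters and 2 with voom weights. Between ALKBH5 and control (16), 28 were called with no filter, 29 after thinning, 42 from exonic clusters and 29 each with the largest number, a pseudocount of 5 and voom weights. Between ALKBH5 and METTL14 (40), 10 were called from only these groups, 26 without clusters overlapping IgG or water, 74 from exonic clusters, 65 with the largest number and 61 with a pseudocount of 5.

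For regions between METTL14 and control (7), 33 were called with no filter, 2 after thinning, 16 with a pseudocount of 5 and 0 with limma voom weights. Between ALKBH5 and control (24), 125 were called with no filter, 10 from only these groups, 15 without clusters overlapping IgG or water, 61 with a pseudocount of 5 and 12 with voom weights. Between ALKBH5 and METTL14 (40), 151 were called with no filter, 24 with the largest number and 85 with a pseudocount of 5. With IP libraries thinned to the smallest of them, gene-level IP versus input called 2160 genes. The lists called by camera became 0 with an estimated correlation and 0 with fry in both ALKBH5 comparisons.

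With the replicate number as a block, 4, 36 and 82 genes were called for METTL14 against control, ALKBH5 against control and ALKBH5 against METTL14, 5, 20 and 40 regions, and 0, 3 and 2 lists. The labels name no shared batch for a number, and not every same-numbered pair correlated by over 0.1: the correlations ran from −0.00684 to 0.212 over genes and from −0.0140 to 0.0334 over regions. A library correlated best with its own number in 13 of 18 cases over genes and 7 of 18 over regions, a hint from the data, not from the design, that some numbers may share a condition.

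With each library left out in turn, the genes called between METTL14 and control ranged from 0 to 4 (0 without control 2, 4 without ALKBH5 1, 2 without control 3). Between ALKBH5 and control they ranged from 2 to 48 (3 without control 1, 2 without control 2 or ALKBH5 2, 8 without control 3, 48 without ALKBH5 1). Between ALKBH5 and METTL14 they ranged from 8 to 74 (16 without control 1, 18 without control 2, 17 without METTL14 1 or 2, 10 without METTL14 3, and 74, 8 and 14 without ALKBH5 1, 2 and 3). Regions ranged from 2 to 20 (20 without control 1, 2 without METTL14 1, 4 without METTL14 3), from 16 to 31 and from 24 to 42 (24 without METTL14 1, 25 without ALKBH5 2, 26 without ALKBH5 3) in the same order. Lists ranged from 0 to 1 (1 without METTL14 2 or 3), from 0 to 3 (0 without control 1 or ALKBH5 3, 1 without control 2, control 3, METTL14 2 or METTL14 3) and from 1 to 3 (1 without METTL14 3 or any ALKBH5 library, 3 without METTL14 2). With 1 of the 2 inputs left out, IP against input called 5068 genes (without the control input) and 5634 (without the ALKBH5 input).

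Of the 9 fits with a library left out, the ALKBH5 to control call was lost in 0 for ADAM19, 2 for NNAT, 3 each for PKIB, THBS4, LINGO1 and COL5A1, 4 for ATOH8, 5 each for VIPR1, PLAT, IGF2 and OBP2A, and 6 each for PRRX2 and CELSR3. Against METTL14 it was lost in 0 for IGF2, 4 for S100A2 and PLIN4, 5 for CHODL, 7 for PKIB, and 8 for TMOD1 and IGF2-AS. Among regions it was lost in 0 for MT-ND3, ACTG1, IGF2 and COL1A1, 2 for EID1 and COL6A2, 7 for PDE7B and 8 for PCYT2. All of these regions stood at 0 in every library of a group, so leaving out a library could not test the spread of that group.

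Single genes whose sign turned had not passed over all genes in any comparison with control, though EIF4A1 had passed adjusted over the list alone. For METTL14 against control these were VWF with at least 5 reads (log2 fold 0.50) and a pseudocount of 5 (0.12), and JUND with the largest number (0.15). For ALKBH5 against control they were BAK1 (−0.40) and CD68 (0.24) with at least 5 reads, CD68 with the largest number (0.16) and EIF4A1 with the gene named in the files (0.23). With a library left out, VWF ranged from −1.37 to 0.95 (highest without METTL14 1) and NGFR from −0.87 to 0.14 (highest without control 3) for METTL14. For ALKBH5, VWF ranged from −1.11 to 0.75 and CD68 from −0.39 to 0.075 (both highest without ALKBH5 2; CD68 0.041 without ALKBH5 3).

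With each cluster counted once, the 3' UTR share of ALKBH5 minus METTL14 was 2.14 points, the stop codon share of ALKBH5 minus control 0.250 and of ALKBH5 minus METTL14 0.756. The DRACH share of clusters ALKBH5 minus control was −0.0824 in a 25 nt window and −0.0330 after subtracting the upstream share. The replicate overlap difference was 0.468 (permutation p = 0.0357) with the same number of top clusters per library.

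With a library left out, ALKBH5 minus control ranged from −60482 to 62604 clusters, from −1087297 to 611919 reads and from −1487620 to 1660139 nt covered, each lowest without ALKBH5 3 and highest without ALKBH5 1. The stop codon share ranged from −0.699 to 0.180 points for METTL14 minus control and from −0.697 to 0.183 for ALKBH5 minus METTL14. The DRACH share ranged from −0.402 to 0.0691 for METTL14 minus control and from −0.135 to 0.349 for ALKBH5 minus control. The background overlap ranged from −3.88 to 2.19 for METTL14 minus control, from −0.367 to 4.10 for ALKBH5 minus control and from −0.212 to 6.25 for ALKBH5 minus METTL14. The replicate overlap difference ranged from −0.290 (without ALKBH5 2) to 0.736, with −0.229 without ALKBH5 3.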

Other observations

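The tests chosen only after the result was seen were that of narrow stacks and those of other splits of the samples; the genes of the next paragraph were also chosen after their values were seen.

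The IGF2 locus held more called regions than any other locus with several. Between ALKBH5 and control 7 regions between 2129441 and 2137296 of chromosome 11 were lower, and between ALKBH5 and METTL14 14 regions between 2129317 and 2139161 were lower. Regions of THBS4 (3) and of S100A4 (2), a calcium-binding protein gene, were higher in ALKBH5 than in METTL14. MYCN, the oncogene amplified in many neuroblastomas, stood at 2707, 2193 and 1689 RPM in control IP, at 2090, 2440 and 1909 in METTL14 IP and at 2530, 1682 and 1658 in ALKBH5 IP, with 2666 in the control input and 1850 in the ALKBH5 input. Its neighbour DDX1, an RNA helicase gene, stood at 4592, 6177 and 4277 RPM in control IP, 8752, 7608 and 6087 in METTL14 IP and 4296, 6418 and 6912 in ALKBH5 IP.

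The 15 genes called between ALKBH5 and control besides ALKBH5 may differ in transcript abundance, in m6A or in both. A narrow stack of reads was argued against as the general source, since 1 of 43 called genes had over 90% of its reads in a block of at most 40 nt. Abundance stays open, and the inputs mostly went with it. The single inputs moved with the IP in 12 of 13 genes with input reads, against 52.0% of all 9762 genes with input reads. The input ratio was larger in size than the IP fold for COL5A1, PRRX2, ATOH8, PLAT, THBS4, NNAT and PKIB. It was smaller for IGF2, CELSR3, VIPR1, LINGO1 and ADAM19 and opposite in sign for SPATS2L. Some of these ratios rest on few input reads. With 1 input per group this has no replicate check, a change in m6A beside the abundance was not tested, and the biological difference between the groups stays open. In 10 splits of the 6 libraries the share can never fall under 0.1; the real split called 16 genes and the highest other 1, so 1 split reached the real count.

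The regions with many reads in 1 group and 0 in every library of another may reflect the caller's reporting floor. There were 60 pairs of region and library at 0, over 19 regions. In 81.7% of them the reads expected from the other group exceeded 2 times the lowest number reported in that gene. This cannot decide on the floor, because the regions were picked as called, which needs many reads in the other group. The expected reads also took transcript abundance as equal, and the set included coding regions of the delivered genes ALKBH5 and METTL14. Pairs of the same region are not independent. No region was tested by itself, and the floor stays open. The ratio of expected reads to that lowest number was at most 0.873 for MT-ND3 and was as low as 1.15 for EID1, 1.29 for COL6A2, 1.60 for ACTG1, 0.768 for CKB and 0.772 for DDX1. Whether the caller divided touching clusters at other places in each library was not tested, and the biological difference between the groups stays open.

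The other comparisons had 10 splits each too, too few for a share under 0.05. METTL14 against control called 1 gene in the real split and at most 0 in another, and ALKBH5 against METTL14 called 40 and at most 0. Regions numbered 7 against at most 4 for METTL14 and control, 24 against at most 9 for ALKBH5 and control, and 40 against at most 3 for ALKBH5 and METTL14.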
